A study of Mus musculus with 3 samples.

How the data were processed

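Nuclei were isolated from 120 mg of frozen liver per library, sorted on DAPI and run on the 10x Genomics platform with 3' chemistry, per the labels' protocols. The deposited values are raw UMI counts per gene and nucleus that the authors made with Cell Ranger 6.1.2, per the file headers. Seurat 4.4.0 and the builds mm10 and GRCm38 are named in the submitters' processing notes without a role; the annotation release, the treatment of introns, and any removal of free RNA or doublets by the authors are not given in the sources used here. The files hold 32285 features, of which 32158 were found in the GRCm38 annotation that gave the coordinates. The groups were taken from the sample labels, with 1 library per group: SD, MASLD and Aza-TdC.

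Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept. Scrublet, run per library with an expected rate of 0.06, called 1, 0 and 6 doublets in SD, MASLD and Aza-TdC, far under that rate, so doublet calling did not work here and doublets largely remain. The filter left out 0, 202 and 7 barcodes, and 7138, 6726 and 7585 nuclei were kept. The 3 libraries were clustered together without integration (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with 3000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 18 clusters.

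Clusters were named from markers of 13 classes fixed before the data were examined. A cluster took the class other than hepatocyte with the highest median log2 ratio of its markers' CPM to all other nuclei, where that median was at least 3 and at least 3 markers were at least 2 times higher. Otherwise it was taken as hepatocyte-like, the default class, if at least 3 hepatocyte markers stood at 0.25 or more of their highest CPM over clusters. A cluster lost its name where its 10 leading genes held more markers of another class than of its own, or where it was shallow with no marker among them. The naming rule was changed 3 times after clusters had been seen. The first version used the mean fold over all other nuclei, the next the share of markers at 0.25 of their highest level, the next a median log2 of 2, and the last a median log2 of 3 together with passing over a leading marker of another class whose highest level lies outside that class. Without that last step clusters 13 and 14 would have no name, and 6.39% of kept MASLD nuclei would be hepatocyte-like. The alternative that names nuclei by their own markers was first computed with standardized levels and then replaced by the planned rule. Cluster 16, with 74 MASLD and 77 Aza-TdC nuclei, stayed without a name and entered no class.

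UMIs were summed over the nuclei of a class and scaled to CPM within the class. Ratios are log2 ratios of CPM with exact conditional binomial 95% intervals, levels have exact Poisson intervals, and shares have exact Clopper-Pearson intervals. A ratio to 0 UMIs is a lower bound against a floor of 3 counts. For each of 35 gene lists fixed beforehand, members with at least 20 UMIs over both libraries were measured, members with a log2 ratio of at least 1 or at most -1 and an interval excluding 0 were counted, and the median was set among 10000 random lists of the same size matched on expression in 20 bins; lists with under 5 measured members got no median. Median intervals are order-statistic intervals over members.

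Genes were named by a rule fixed before the data were examined. In hepatocyte-like nuclei these were the 12 highest and 12 lowest ratios by the interval bound nearest 0 with at least 50 UMIs in the higher library, up to 4 members of each list, and Dnmt1, Klb, Fgf21 and Fgfr1. In other classes with at least 100 nuclei in both libraries they were the 5 highest and 5 lowest with at least 30 UMIs, leaving out genes with a higher level in hepatocyte-like nuclei. Unnamed transcripts and mitochondrial genes were passed over, and some genes the rule names are not reported here. The correlation between comparisons used genes with at least 100 UMIs and 100 simulations of exchangeable libraries.

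The statistics were tested on simulated data before use. For MASLD against SD, with 15771 genes, 93.6% of log2 changes of 1 and 98.1% of changes of 2 were recovered, 4.63% of unchanged genes had an interval excluding 0, and 95.35% of intervals held the true ratio. For Aza-TdC against MASLD, with 15947 genes, the values were 92.9%, 99.1%, 4.62% and 95.38%. The simulated counts were independent Poisson draws without spread between libraries or free RNA. Coverage near the nominal value therefore follows from the interval itself and says nothing on differences between animals. Random lists fell under percentile 2.5 or over 97.5 in 4.5% and 7.5% of draws, where 5% is nominal. Alternatives to the filters, doublets, resolution, naming, scaling and minimum counts were run one at a time, among them the endothelial-like class without cluster 11. Clusters made without the genes of both macrophage lists changed the resolution, to 2, together with the gene set.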

Results

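Single-nucleus RNA sequencing was carried out on frozen liver of male C57BL/6N mice, 8 weeks old at the start, in 3 libraries, 1 per group. The SD library came from the standard diet. The MASLD library came from a diet that induces metabolic dysfunction-associated steatotic liver disease, given for 18 weeks with a sugar drink. The Aza-TdC library came from the same diet with oral Aza-TdC, a nucleoside analogue that depletes the DNA methyltransferase DNMT1, at 2 mg per kg daily from week 14 to week 18. The SD library held 7139 barcodes and 45162618 UMIs, the MASLD library 6928 barcodes and 43569644 UMIs, and the Aza-TdC library 7598 barcodes and 51789068 UMIs. Median UMIs per barcode were 5849, 5923 and 6383 in the same order. Filters kept 7138, 6726 and 7585 nuclei. Each group had 1 library, whose number of animals is not given in the sources used here, so no test between groups was possible. Intervals below are 95% intervals. Those of shares, levels and gene ratios cover counting error only, and those of list medians show the spread over list members. None covers the spread between animals.

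The comparison of cell classes addressed how the liver's makeup differed with diet and with treatment. Macrophage-like nuclei, led by the Kupffer cell genes Clec4f and Cd5l (cluster 7), made up 0.434% (0.295 to 0.616) of kept nuclei in SD, 3.6% (3.17 to 4.07) in MASLD and 4.22% (3.78 to 4.7) in Aza-TdC. Hepatocyte-like nuclei made up 96.1% (95.6 to 96.5), 89.7% (88.9 to 90.4) and 89.9% (89.2 to 90.6). Endothelial-like nuclei (clusters 5 and 11) made up 1.61% (1.33 to 1.93), 2.68% (2.3 to 3.09) and 2.41% (2.08 to 2.78), and stellate-like nuclei (cluster 4) 1.08% (0.852 to 1.35), 1.58% (1.29 to 1.9) and 1.09% (0.873 to 1.35). Mesothelial-like nuclei (cluster 8) made up 0.406% (0.272 to 0.583), 0.743% (0.552 to 0.979) and 0.778% (0.593 to 1.00). T and NK-like nuclei (cluster 6) made up 0.392% (0.261 to 0.566), 0.61% (0.438 to 0.826) and 0.54% (0.388 to 0.733). The leading genes of cluster 6 also hold the B cell gene Ebf1. It parted at Leiden resolution 2 into T and NK-like (23, 26 and 29 nuclei in SD, MASLD and Aza-TdC) and B-like nuclei (5, 15 and 12). The MASLD share of macrophage-like nuclei divided by the SD share was 8.29 (5.69 to 12.5), and 4.00 (2.71 to 6.04) with at most 1% mitochondrial UMIs per nucleus. Taken over nuclei that are not hepatocyte-like, the direction turned for the other small classes. Shares were then 41.1% in SD against 26% in MASLD for endothelial-like, 27.5% against 15.3% for stellate-like, 10.0% against 5.92% for T and NK-like and 10.4% against 7.21% for mesothelial-like nuclei. Macrophage-like nuclei had 11.1% against 34.9%. The total behind these shares, 280 nuclei in SD and 693 in MASLD, includes macrophage-like nuclei (31 and 242) and cluster 16 (0 and 74). Their higher numbers in MASLD lower the other shares, so the turn does not show that the other small classes fell. The nuclei had been sorted on DAPI, and the smallest barcode held 1546 UMIs in SD against 500 in the other libraries, which can set such shares. With at most 1% mitochondrial UMIs, MASLD shares of the other small classes lay below those of SD. They were 0.727% against 1.53% for endothelial-like and 0.776% against 1.08% for stellate-like nuclei. For mesothelial-like nuclei they were 0.162% against 0.379%, and for T and NK-like nuclei 0.113% against 0.309%. That limit fell mostly on MASLD, where kept nuclei went from 6726 to 6188, against 7138 to 7127 in SD. Endothelial-like nuclei went from 180 to 45 in MASLD and from 115 to 109 in SD. Clustering was redone there and left 142 MASLD and 2 SD nuclei without a name. These lower shares therefore do not show that the classes fell with diet.

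**Figure D1:**
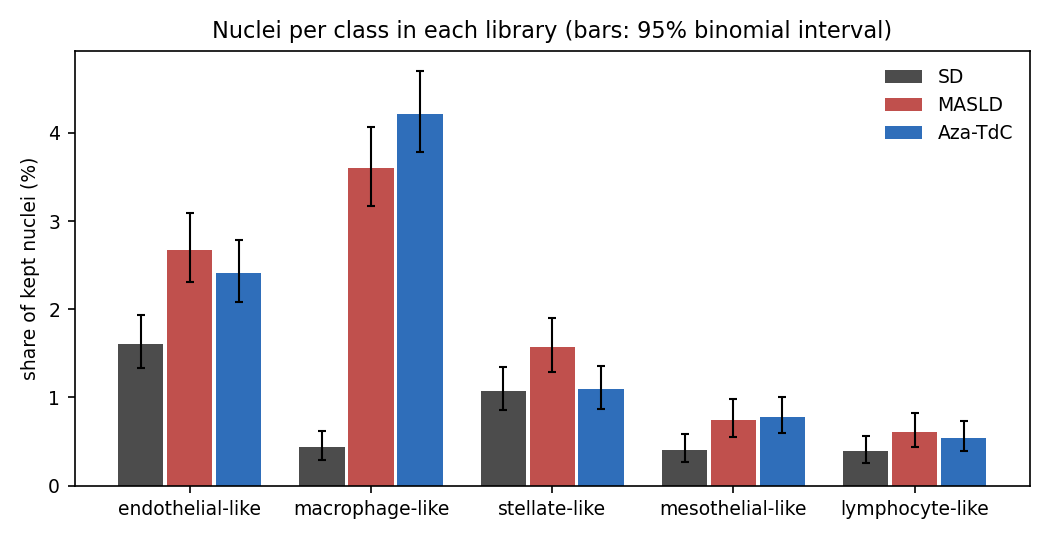
Share of kept nuclei in percent (vertical axis) for the 5 classes other than hepatocyte-like (horizontal axis) in the SD, MASLD and Aza-TdC libraries; error bars are exact binomial 95% intervals over nuclei of 1 library each. The macrophage-like share was 0.434% in SD, 3.6% in MASLD and 4.22% in Aza-TdC.

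Hepatocyte-like nuclei separated by library. Clusters 0 to 3 held nearly all of those in SD, clusters 12, 13, 14 and 17 most of those in MASLD, and clusters 9, 12, 15 and 17 most of those in Aza-TdC. Clusters 13 and 14, with 5603 MASLD, 86 Aza-TdC and 1 SD nuclei, had more leading genes from other classes' marker lists (Cidec, Tox and Pkhd1) than from the hepatocyte list. Hepatocyte-like values are therefore comparisons between these numbered clusters, and a cluster that lies mostly in 1 library may be that library and not a cell type.

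Hepatocyte-like nuclei of the MASLD library (clusters 12, 13, 14 and 17) carried more transcripts of lipid storage and fatty acid uptake than those of SD (clusters 0 to 3). Cidea, which encodes a protein that promotes lipid droplet growth, stood at 38.1 CPM (36.3 to 40.0) in MASLD against 0.429 CPM (0.258 to 0.669) in SD, a log2 ratio of 6.47 (5.83 to 7.21). Cidec, a related lipid droplet gene, had a log2 ratio of 4.14 (4.01 to 4.27), and Cd36, a fatty acid transporter, one of 5.25 (5.11 to 5.40). Fgf21, a hormone secreted by the liver, stood at 67.4 CPM (64.9 to 70.0) against 2.8 CPM (2.33 to 3.33). Several transcripts of glucose metabolism were lower, among them glycogen phosphorylase Pygl at -2.13 (-2.17 to -2.10) and pyruvate kinase Pklr at -1.66 (-1.70 to -1.62).

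The 12 genes with the highest ratios also included Fut2, a fucosyltransferase, at 8.83 (7.28 to 11.11) over 3 UMIs in SD, and Ly6d, which had 0 UMIs in SD and was at least 108-fold higher in MASLD. Fam83a stood at 8.01 (6.15 to 11.06) over 2 UMIs in SD, the phospholipid scramblase gene Plscr4 at 6.35 (5.98 to 6.74), the RNA-binding protein gene Rbfox1 at 6.15 (5.68 to 6.67) and the protease gene Ctse at 5.86 (5.38 to 6.37). Apoa4, an apolipoprotein, had 5.45 (5.32 to 5.58), Ephb2 6.44 (5.31 to 7.89) and Tmem86a 5.83 (5.01 to 6.79). Cyp2a4, a cytochrome P450 more abundant in female liver, had 7.34 (6.11 to 8.97), and reads can be shared with its close copy Cyp2a5. Among the 12 lowest, Nnmt, which methylates nicotinamide, stood at 220.4 CPM in SD and 12.6 CPM in MASLD (log2 ratio -4.13, interval -4.26 to -4.005), and Pdgfrl at 245 and 21.3 CPM (log2 ratio -3.52, interval -3.62 to -3.42). Srgap3 had -5.70 (-6.46 to -5.03), the actin-binding protein gene Avil -5.15 (-6.07 to -4.36), the male-biased steroid enzyme gene Hsd3b5 -4.32 (-4.80 to -3.87) and the antitrypsin gene Serpina1e -3.55 (-3.66 to -3.43). Pcdh11x, Grid1, Adcy2 and Sema3e ranged from -4.45 to -3.71, and Adgrf1 had 1 UMI in MASLD and -6.01 (-11.33 to -3.48).

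Of the lipid droplet list, 11 of 19 measured members had a log2 ratio of at least 1 and 0 at most -1, with a median log2 ratio of 1.45 (0.37 to 2.29) and a percentile of 100 among 10000 random lists matched on expression. Mogat1, an acyltransferase of triglyceride synthesis, had 3.05 and Fitm1 2.31. Of the list of fatty acid uptake and PPARG targets, 11 of 14 measured members had a log2 ratio of at least 1 and 0 at most -1 (median 2.59, interval 0.79 to 4.85, percentile 100), with lipoprotein lipase Lpl at 4.85 (3.78 to 6.18) and Anxa2 at 4.39 (3.69 to 5.19). Of the PPARA targets and fatty acid oxidation genes, 13 of 30 measured members had a log2 ratio of at least 1 and 0 at most -1 (median 0.68, interval 0.35 to 1.89, percentile 100), among them Pdk4 at 4.10, Acot2 at 4.08 and Cyp4a31 at 4.78, the last with close copies in its family. De novo lipogenesis genes went both ways, 9 higher and 4 lower of 24 (median 0.21, interval -0.68 to 1.37), with the desaturase gene Scd1 at 3.49, the elongase gene Elovl5 at 2.70 and the lipase-like gene Pnpla3 at 3.33. Of the glucose metabolism and insulin signalling list, 3 of 25 measured members had a log2 ratio of at least 1 and 7 at most -1 (median -0.39, interval -0.93 to -0.023, percentile 0), and the glucose-6-phosphatase gene G6pc stood at -1.39. The list of nuclear and RNA quality signs was also higher in MASLD, with a median of 0.90 (0.58 to 1.52) and percentile 100, Tmsb4x at 2.86, Actb at 1.90 and mt-Cytb at 1.52. The median mitochondrial share of hepatocyte-like nuclei was 0.124% in SD, 0.189% in MASLD and 0.082% in Aza-TdC.

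Several stress and proliferation lists also stood high in MASLD against matched random lists, at percentiles of 100 (NRF2), 99.9 (unfolded protein), 100 (cell cycle), 100 (immediate early) and 99.9 (acute phase). The p53 and interferon lists, at 87.1 and 93.8, did not stand apart. Extreme percentiles were not particular to stress, proliferation and lipid lists. In the same comparison the female-biased and secreted plasma protein lists stood at 100, capillarization at 99.9 and the periportal list at 0.1. The NRF2 and glutathione list had a median of 0.88 (0.36 to 2.21) with 9 of 20 members at 1 or more, among them the glutathione transferase gene Gsta1 at 4.62 (3.61 to 5.86). The unfolded protein and integrated stress response list had a median of 0.61 (0.11 to 1.34), led by the stress-induced gene Nupr1 at 5.05 (4.19 to 6.07). The cell cycle list had a median of 0.996 (0.20 to 1.16) with 15 of 30 members at 1 or more, at low levels such as 1.62 against 0.451 CPM for the topoisomerase gene Top2a. The p53 target and DNA damage list had 0.32 (0.14 to 1.20), with Gdf15 at 3.21 and Cdkn1a at 2.11. Immediate early genes had 0.999 (-0.036 to 2.01), with Klf6 at 3.38 and Jun at 2.01. The acute phase and inflammation list had 0.51 (-0.16 to 1.53), with Apcs at 3.30 and Saa2 at 1.96; the chemokine gene Ccl2 had 0 UMIs in SD and was at least 17.1-fold higher. Interferon response genes had 0.46 (0.13 to 1.08), with Cxcl10 at 2.84. The RNA quality list was higher as well, and its median was 0.34 in nuclei matched for mitochondrial share, at most the lowest library's median, in place of 0.90. The list holds mitochondrial genes, which this matching by itself evens out between libraries.

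Zonation, sex-biased and identity genes differed by member. The periportal list had a median of -0.35 (-1.47 to 0.35), with the urea cycle gene Ass1 at -2.27 (-2.30 to -2.25) and Cdh1 at 2.87 (2.36 to 3.41), and the pericentral list 0.12 (-0.28 to 0.51), with Cyp2c54 at -2.12. With clusters 13 and 14 left out of the class, as a strict reading of their leading genes asks, these medians were -1.68 and 1.79. Of the 430 MASLD nuclei then left, 328 lay in cluster 12, led by the pericentral genes Slc1a2, Lgr5 and Glul. Thus a pericentral cluster was set against all SD hepatocyte-like nuclei. The female-biased list had 1.29 (-0.48 to 3.06), with Cyp4a14 at 3.30 and Cux2 at -3.505, and the male-biased list 0.17 (-0.23 to 1.30), with Cyp4a12a at 3.69 and Mup20 at 2.94, a member of a family of near-identical genes. The transcription factor list had -0.020 (-0.25 to 0.46), with Onecut1 at -1.78, and the dedifferentiation and ductular list 0.62 (0.10 to 1.23), with Spp1 at 6.12 (4.88 to 7.75). Sox4 had 0 UMIs in SD and was at least 8.93-fold higher, over 25 UMIs in MASLD of which 1 lay in nuclei matched for mitochondrial share, too few for a ratio there. Secreted plasma proteins had 0.46 (-0.070 to 0.80), with Ttr at 1.74. Cholesterol synthesis had 0.19 (-0.17 to 0.57), with Hmgcs1 at 1.30 and Sqle at -1.25. Bile acid and sterol handling had 0.29 (-0.23 to 0.73), with Cyp8b1 at 2.83 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.85. The list of CAR, PXR and AHR cytochromes had 0.24 (-0.49 to 0.92), with Cyp2b10 at -1.37. The circadian list had 0.014 (-0.58 to 0.49). Imprinted and oncofetal genes had 0.10 (-1.49 to 1.42), with Peg3 at 2.66 and Meg3 at -2.53.

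Lists of other cell types, read in hepatocyte-like nuclei where free RNA contributes, had medians of 2.21 (0.90 to 4.47) for lipid-associated and recruited macrophages, 0.59 (0.089 to 1.17) for Kupffer identity, 0.76 (0.36 to 1.22) for fibrosis and matrix, 0.32 (-0.19 to 1.44) for stellate quiescence, 0.60 (-0.038 to 0.74) for sinusoidal endothelium and 1.26 (-0.21 to 2.83) for endothelial capillarization. The sinusoidal median was -0.10 in nuclei matched for mitochondrial share and -0.041 with clusters 13 and 14 left out of the class. The T cell list, with 5 members measured, had 0.95 (-2.82 to 2.85). Some genes belong to more than 1 list, among them Cd36 and Lpl. Cyp4a10, Cyp4a14 and Acot3 belong to both the PPARA target and the female-biased lists. Across all measured genes the median log2 ratio in hepatocyte-like nuclei was 0.15 with scaling to the total and 0.023 with median-ratio scaling, a shift of -0.13, so ratios are read relative to that level.

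In stellate-like nuclei (77 in SD, 106 in MASLD), the fibrosis and extracellular matrix list had a median of 0.82 (0.19 to 1.22), with 11 of 27 measured members at 1 or more and 0 at -1 or less, and the stellate quiescence list had 0.23 (-0.075 to 1.09). With at most 1% mitochondrial UMIs the fibrosis median was 0.13, with 2 members at 1 or more, and the quiescence median -0.078. The count was 5 with hepatocyte RNA subtracted, 7 with classes by each nucleus's own markers, and 3 at a minimum of 100 UMIs, which left 6 members measured. Hemoglobin transcripts moved together with the fibrosis list in the same nuclei, with Hbb-bs at 16.9 CPM in SD and 374 CPM in MASLD and Hba-a1 at 4.23 and 240.5 CPM. In macrophage-like nuclei (31 in SD, 242 in MASLD), the lipid-associated and recruited macrophage list had a median of 1.44 (0.84 to 2.80), with 14 of 23 measured members at 1 or more and 0 at -1 or less, and the Kupffer identity list had -0.16 (-0.81 to 0.89). At Leiden resolution 2, where 18 of the SD and 106 of the MASLD nuclei kept the name, 6 members of the recruited list stood at 1 or more. These classes held under 100 nuclei in SD, so no single genes are named for them. In endothelial-like nuclei (115 in SD, 180 in MASLD; clusters 5 and 11) the sinusoidal identity list had a median of 0.063 (-0.30 to 0.87) and the capillarization and activation list 0.71 (-0.34 to 2.83). With at most 1% mitochondrial UMIs the sinusoidal median was -0.43 and the capillarization median -0.26. Lyve1, a sinusoidal receptor gene, had a log2 ratio of 1.48 (0.85 to 2.16), Fcgr2b 1.36 (1.02 to 1.71), Plvap 4.41 (1.83 to 9.76) over 1 UMI in SD, and Ly6a 5.25 (2.71 to 10.57) over 1 UMI. Entpd1 had -3.17 (-4.57 to -2.004), Pgm5 -2.59 (-3.83 to -1.505), Dnm3 -2.32 (-3.39 to -1.36) and Gna14 -1.87 (-2.81 to -0.999). The Wnt agonist gene Rspo3 had -1.05 (-1.56 to -0.56) and Nrg1 -2.17 (-3.37 to -1.10). With cluster 11 left out of the class (13 SD and 5 MASLD nuclei), an alternative chosen after seeing the data, Rspo3 had 2.98 over 2 UMIs in SD and Nrg1 2.60 over 1 UMI. Entpd1 and Dnm3 then had 1 UMI in each library, and the list medians were 0.38 and 1.97. The 5 highest genes, Apoa4, Scd1, Mup17, Mup20 and Hbb-bs, are best known from hepatocytes or red blood cells, and hepatocyte markers stood in endothelial-like nuclei at 0.587 times their hepatocyte level in SD and 0.818 times in MASLD (median of 20 markers). T and NK-like nuclei had 2 measured members of their list, too few for a median.

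**Figure D2:**
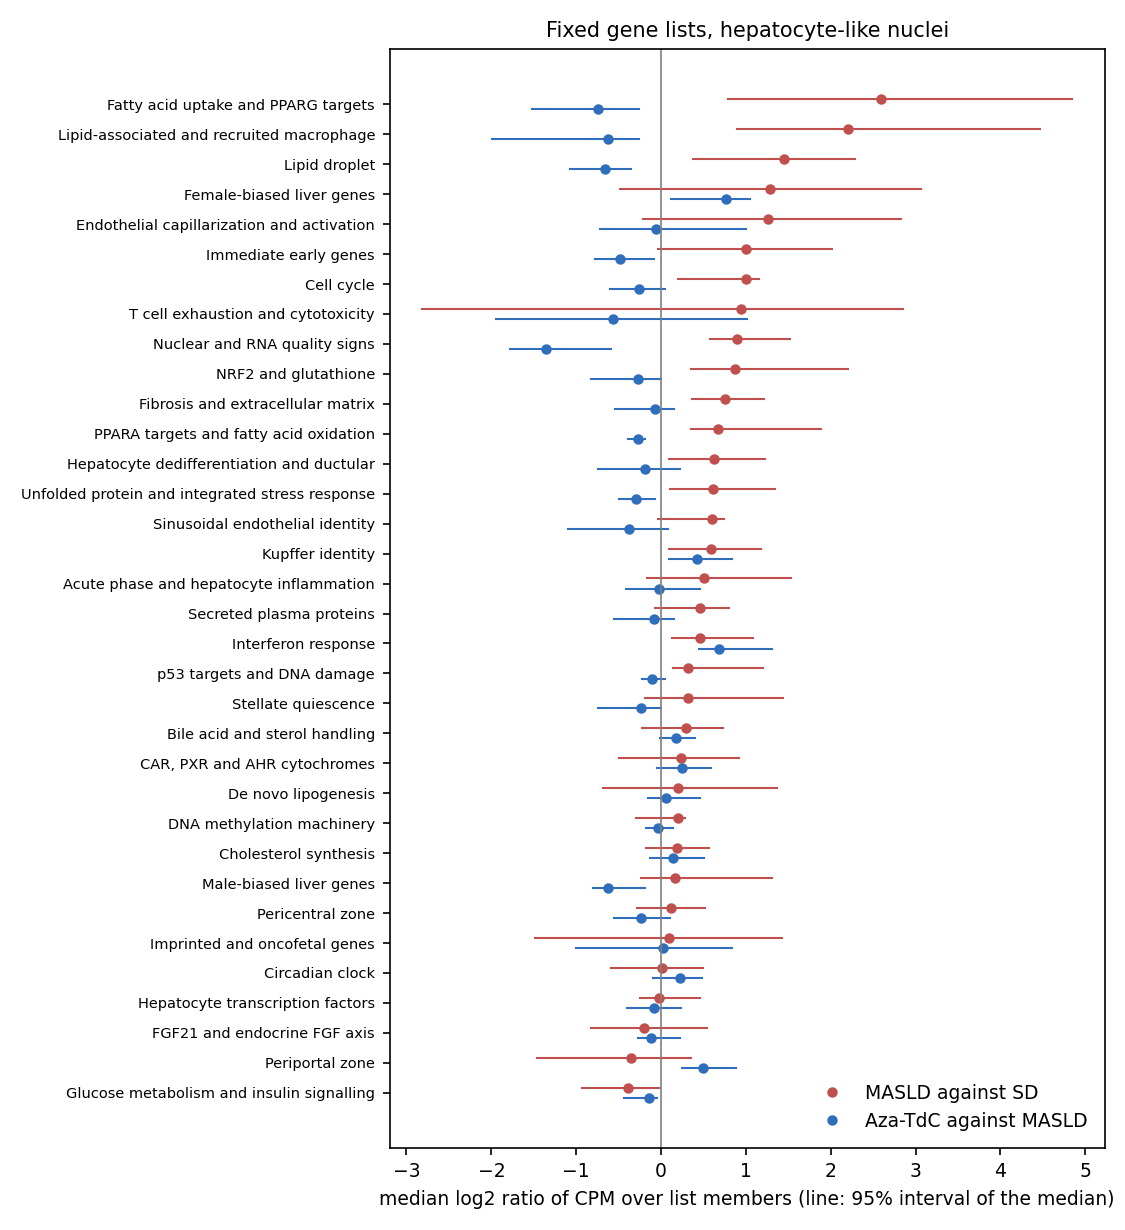
Median log2 ratio of CPM over the measured members of each fixed gene list in hepatocyte-like nuclei (horizontal axis; lists on the vertical axis), for MASLD against SD and for Aza-TdC against MASLD, with 1 library per group; lines are 95% order-statistic intervals over list members. The list of fatty acid uptake and PPARG targets stood at 2.59 and -0.74, and the interferon response list at 0.46 and 0.68.

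The comparison of Aza-TdC with MASLD asked how treatment during the disease diet differed from the diet alone. In hepatocyte-like nuclei (clusters 9, 12, 15 and 17 in Aza-TdC; 12, 13, 14 and 17 in MASLD), Cidea stood at 0.584 CPM (0.391 to 0.838) in Aza-TdC, a log2 ratio of -6.03 (-6.61 to -5.501) to MASLD and of 0.45 to SD. Cux2, a female-biased transcription factor gene in liver, stood at 57.2 CPM (55.1 to 59.4) against 0.145 CPM (0.053 to 0.316) in MASLD, a log2 ratio of 8.62, and at 1.65 CPM (1.29 to 2.07) in SD. Interferon-induced genes were higher, among them Zbp1 at 2.92 (2.62 to 3.24) and Gbp3 at 3.56 (2.93 to 4.25), and so were the metallothionein genes Mt1 at 2.38 (2.31 to 2.45) and Mt2 at 3.46 (3.31 to 3.61). Genes of lipid uptake and storage were lower, with Fabp1, the liver fatty acid-binding protein gene, at -1.52 (-1.53 to -1.500) and Cidec at -1.30 (-1.35 to -1.25).

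Others among the 12 highest were the interferon-inducible GTPase genes Gvin1 at 5.25 (4.31 to 6.39) and Tgtp1 at 5.46 (2.92 to 10.79) over 1 UMI in MASLD, the glutamate receptor gene Grm8 at 2.69 (2.62 to 2.77), the activin receptor gene Acvr2b at 2.36 (2.26 to 2.47), Pld4 at 2.79 (2.23 to 3.39), Tafa1 at 3.09 (2.32 to 3.96) and Tmc5 at 3.93 (2.31 to 6.25) over 3 UMIs. Among the 12 lowest were the major urinary protein genes Mup17 at -4.23 (-4.42 to -4.05), Mup18 at -4.497 (-5.02 to -4.01) and Mup11 at -3.51 (-3.70 to -3.33), whose near-identical sequences make the split of reads uncertain. Kbtbd11 had -3.82 (-4.68 to -3.06) and Limch1 -3.83 (-4.73 to -3.04). The list also held transcripts of other cells: the hemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, at 8.21, 148 and 13.8 CPM for Hbb-bs in SD, MASLD and Aza-TdC, and the pancreatic enzyme genes Cpb1 and Ctrb1, with 75 and 55 UMIs in MASLD and 0 in the other libraries. Cpb1 was at least 30.3-fold and Ctrb1 at least 22.2-fold lower in Aza-TdC.

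**Figure D3:**
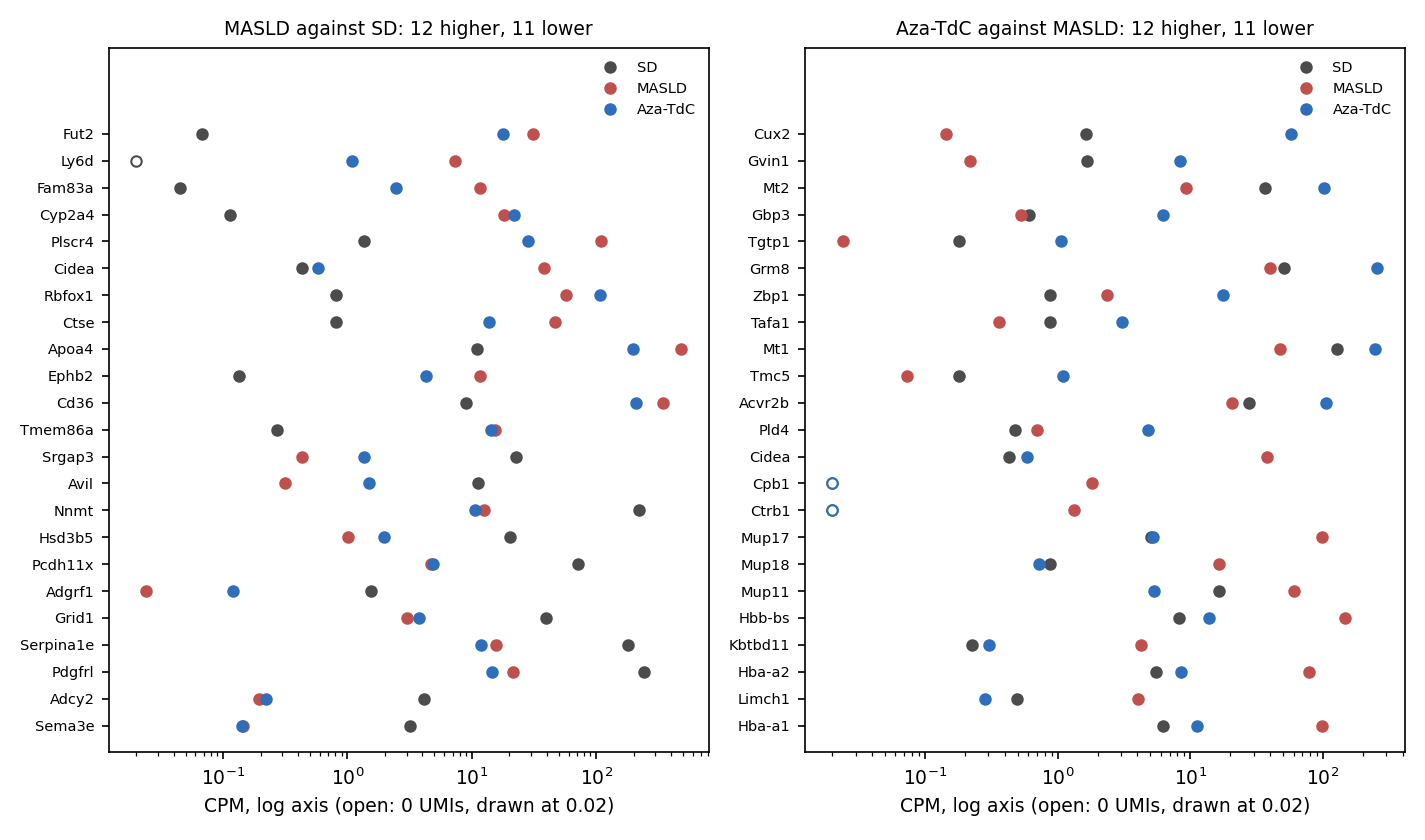
CPM in hepatocyte-like nuclei (horizontal log axis) of the 12 genes with the highest log2 ratio and 11 of the 12 with the lowest in each comparison (vertical axis), in the SD, MASLD and Aza-TdC libraries, 1 point per library without error bars; open points had 0 UMIs. Cidea stood at 0.429, 38.1 and 0.584 CPM.

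Of the lipid droplet list, 1 of 19 measured members had a log2 ratio of at least 1 and 6 at most -1 (median -0.67, interval -1.07 to -0.35, percentile 0), with Fitm1 at -1.69 and Mogat1 at -1.23. Fatty acid uptake and PPARG targets had 0 members at 1 or more and 6 at -1 or less of 14 (median -0.74, interval -1.52 to -0.26, percentile 0), with Anxa2 at -3.000 and Fabp4 at -2.10. PPARA targets and fatty acid oxidation had -0.27 (-0.39 to -0.18); Vnn1 stood at -1.22 and Ehhadh at -0.87, while Cyp4a10 stood at 1.04 and Cyp4a14 at 0.97. Against SD, the medians in Aza-TdC were 0.62 (0.023 to 1.20) for lipid droplet, 0.99 (0.41 to 4.16) for uptake and 0.42 (0.17 to 2.01) for oxidation genes. De novo lipogenesis had 0.055 (-0.15 to 0.46), with Pnpla3 at 1.79, and glucose metabolism and insulin signalling -0.15 (-0.43 to -0.052), with Pklr at -1.63 and the glycogen synthase gene Gys2 at -1.25. Median-ratio scaling, which moved the median gene by 0.096, brought the oxidation and glucose medians to -0.17 and -0.051. The list of RNA quality signs was lower too, with a median of -1.35 (-1.78 to -0.59), percentile 0 and mt-Cytb at -1.98; in nuclei matched for mitochondrial share its median was -0.38, and those of the lipid droplet and uptake lists were -0.71 and -0.68.

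Of the interferon response list, 11 of 30 measured members had a log2 ratio of at least 1 and 1 at most -1 (median 0.68, interval 0.45 to 1.30, percentile 100), with Igtp at 2.33 and Oas1a at 2.25; in nuclei matched for mitochondrial share 6 members stood at 1 or more. Of the female-biased list, 5 of 16 measured members had a log2 ratio of at least 1 and 1 at most -1 (median 0.77, interval 0.12 to 1.04), with Slc22a26 at 3.005, and of the male-biased list, 0 of 23 measured members had a log2 ratio of at least 1 and 5 at most -1 (median -0.62, interval -0.80 to -0.19), with Selenbp2 at -2.29. The female-biased count at 1 or more was 8 with median-ratio scaling and 1 with clusters 13 and 14 left out, where 11 male-biased members lay at -1 or less. The periportal list had 0.49 (0.24 to 0.89), with Etnppl at 1.502 and Pigr at 1.39, and the pericentral list -0.23 (-0.56 to 0.11), with Oat at -1.37 and Cyp2c54 at 1.63. With clusters 13 and 14 left out, so that MASLD is mostly the pericentral cluster 12, these medians were 1.64 and -2.35, the interferon median was 0.37 with 5 members at 1 or more, and Cyp2c54 and Cyp2c29 stood at -0.38 and -0.78. The circadian list had 0.23 (-0.097 to 0.49), with the clock genes Arntl at 1.42 and Cry1 at 1.28 and with Bhlhe41 at -1.82; the hour of tissue collection is not given in the sources used here. The list of CAR, PXR and AHR cytochromes had 0.25 (-0.048 to 0.59), with Cyp3a11 at 1.34 and Cyp2c29 at 1.25, and -0.073 with clusters 13 and 14 left out. Cholesterol synthesis had 0.14 (-0.13 to 0.51), with Sqle at 1.495, and bile acid and sterol handling 0.18 (-0.011 to 0.40), with the nuclear receptor gene Nr0b2 at 1.01. The percentile of 100 was not particular to the interferon list. The female-biased, periportal, circadian and CAR, PXR and AHR lists also had 100, and the male-biased list had 0.

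The unfolded protein and integrated stress response list had -0.29 (-0.501 to -0.073), with the asparagine synthetase gene Asns at 2.29 and Sdf2l1 at -1.44. NRF2 and glutathione genes had -0.27 (-0.83 to 0.003), with Gsta1 at -1.88 and the transporter gene Abcc4 at 1.39. Immediate early genes had -0.48 (-0.78 to -0.085), with Jun at -1.07, and p53 targets -0.10 (-0.22 to 0.048), with Gdf15 at -1.18 and Eda2r at -1.49. Cell cycle genes had -0.26 (-0.60 to 0.042), with Mki67 at -1.44 (-2.15 to -0.76), and acute phase genes -0.025 (-0.41 to 0.45), with Saa2 at -1.62 and the fibrinogen gene Fgg at 1.18. Secreted plasma proteins had -0.080 (-0.56 to 0.15), with Apoc3 at -1.08 and Mug1 at 0.90. Transcription factors had -0.077 (-0.40 to 0.23), with Onecut1 at -1.30 and the estrogen receptor gene Esr1 at 1.14. The dedifferentiation and ductular list had -0.19 (-0.74 to 0.22), with Krt23 at -2.40, and imprinted and oncofetal genes 0.029 (-1.01 to 0.83), with Meg3 at -1.22. With clusters 13 and 14 left out, the medians were -0.78 for the unfolded protein, -0.65 for the cell cycle and -0.81 for the dedifferentiation list, and Abcc4 changed sign. Read in hepatocyte-like nuclei, the lists of other cell types had -0.62 (-1.99 to -0.26) for lipid-associated and recruited macrophages, 0.42 (0.098 to 0.84) for Kupffer identity, -0.071 (-0.55 to 0.15) for fibrosis, -0.24 (-0.75 to -0.001) for stellate quiescence, -0.38 (-1.10 to 0.077) for sinusoidal endothelium (0.098 in nuclei matched for mitochondrial share), -0.056 (-0.72 to 0.999) for capillarization and -0.56 (-1.94 to 1.01) for T cells.

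Genes tied to the study's title were measured in the same nuclei. Dnmt1, the maintenance DNA methyltransferase (GRCm38 chromosome 9, 20907209 to 20959888, minus strand), stood at 7.74 CPM (6.94 to 8.6) in SD, 8.99 CPM (8.1 to 9.95) in MASLD and 9.9 CPM (9.05 to 10.8) in Aza-TdC, with log2 ratios of 0.22 (0.001 to 0.43) and 0.14 (-0.058 to 0.34). The transcript level does not measure DNMT1 protein, which is what the drug depletes. The DNA methylation machinery list had medians of 0.20 (-0.30 to 0.28) and -0.037 (-0.18 to 0.14), with Gadd45a, a growth arrest gene, at 2.28 and -0.54 and Dnmt3b at 0.61 in the second. Klb, the FGF21 co-receptor gene (chromosome 5, 65348314 to 65384007, plus strand), stood at 79.9 CPM (77.2 to 82.5), 60.4 CPM (58.1 to 62.8) and 55.7 CPM (53.6 to 57.8), with log2 ratios of -0.40 (-0.48 to -0.33) and -0.12 (-0.20 to -0.039). Fgf21 (chromosome 7, 45613886 to 45615490, minus strand) had 4.59 (4.33 to 4.86) and -0.65 (-0.73 to -0.57), and Fgfr1 -2.86 (-3.78 to -2.05) and 0.45 (-0.57 to 1.52) over 14 UMIs in MASLD. The FGF21 and endocrine FGF list had medians of -0.20 (-0.82 to 0.55) and -0.12 (-0.27 to 0.23). Of the germline genes silenced by promoter methylation, 3 and 4 members were measured, too few for a median. Among them Ddx4 had 7 UMIs in MASLD and 13 in Aza-TdC (log2 ratio 0.63, interval -0.80 to 2.19), and Sycp3 had -0.52 (-0.61 to -0.43).

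In macrophage-like nuclei (cluster 7; 320 in Aza-TdC, 242 in MASLD), genes of resident Kupffer cells were higher in Aza-TdC and genes of lipid-associated and recruited macrophages were lower. The scavenger receptor gene Marco stood at 295 CPM (264 to 329) against 31.6 CPM (20.1 to 47.5), a log2 ratio of 3.22 (2.61 to 3.90), Timd4 at 1.68 (1.40 to 1.97), C6 at 1.42 (1.25 to 1.59) and Cd163 at 1.33 (1.09 to 1.57). Lyz2, a lysozyme gene of myeloid cells, stood at 91.4 CPM (74.3 to 111) against 807 CPM (743 to 875) (log2 ratio -3.14, interval -3.46 to -2.83), the monocyte chemokine receptor gene Ccr2 at -3.26 (-4.02 to -2.57), Cd63 at -3.53 (-4.72 to -2.52), and Spp1 at -4.23 (-7.36 to -2.23) over 2 UMIs. Of the Kupffer identity list, 8 of 16 measured members had a log2 ratio of at least 1 and 0 at most -1 (median 1.001, interval 0.80 to 1.33, percentile 100), and of the recruited list, 0 of 23 measured members had a log2 ratio of at least 1 and 14 at most -1 (median -1.63, interval -2.44 to -0.93, percentile 0). Hemoglobin transcripts moved together with the recruited list in the same nuclei, with Hbb-bs at 22.4, 263 and 32 CPM and Hba-a1 at 11.2, 162 and 32.9 CPM in SD, MASLD and Aza-TdC. At Leiden resolution 2 these nuclei lay largely in different clusters. A macrophage-like cluster led by Clec4f and Cd5l held 106 MASLD and 290 Aza-TdC nuclei. The other 136 and 30 were left without a name, in a cluster led by Cd74, the MHC class II gene H2-Ab1, Lyz2 and Gpnmb. Its markers scored higher for dendritic than for Kupffer cells (median log2 ratio to all other nuclei 4.95 against 4.60). Lyz2 and Gpnmb, however, are among the fixed macrophage markers. In the macrophage-like cluster the medians were 0.38 and -0.91, with 1 Kupffer identity member at 1 or more and 7 recruited members at -1 or less. With at most 1% mitochondrial UMIs the medians were 0.56 and -1.17, with 2 Kupffer identity members at 1 or more.

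The same cluster held nuclei with dendritic cell genes in SD and MASLD. Flt3, a dendritic progenitor receptor gene, had 15, 54 and 0 UMIs in SD, MASLD and Aza-TdC and was at least 27-fold lower in Aza-TdC than in MASLD. Bcl11a was at least 25-fold lower and Dscam and Ccser1 at least 19.2-fold lower. With Leiden resolution 2, with classes by each nucleus's own markers and with no doublets left out, these 4 genes had at most 3 UMIs in each library, too few for a ratio. Ltbp1 had -6.37 (-11.70 to -3.83) over 1 UMI. The other highest genes were Tshz2 at 3.98 (3.33 to 4.70), Dgki at 3.37 (2.64 to 4.20), Gfra2, a neurturin receptor gene, at 3.45 (2.58 to 4.48), and Tmc3 at 4.995 (3.103 to 8.06) over 2 UMIs in MASLD.

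**Figure D4:**
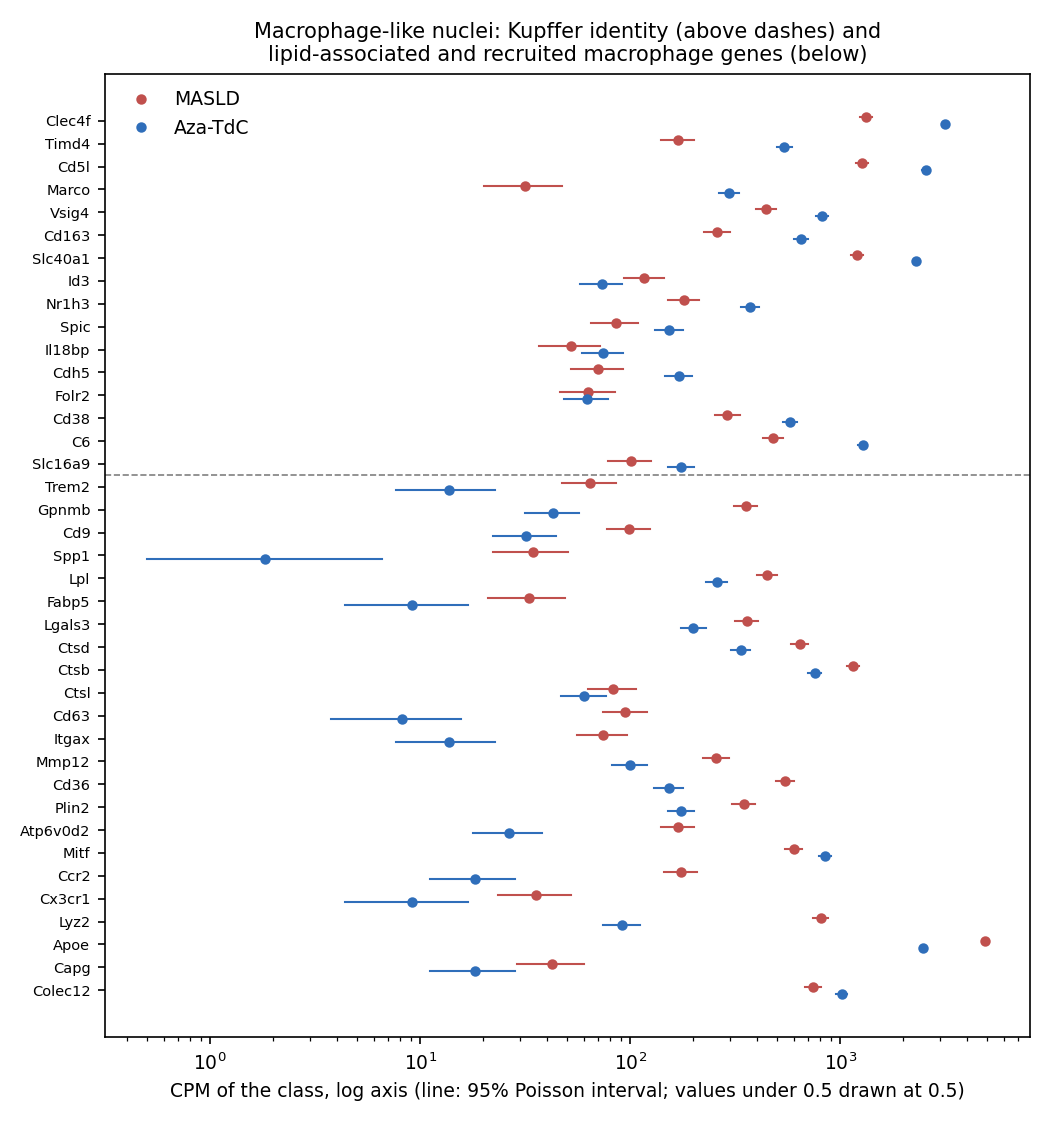
CPM in macrophage-like nuclei (horizontal log axis) of the measured members of the Kupffer identity list (above the dashed line) and of the lipid-associated and recruited macrophage list (below it), in the MASLD and Aza-TdC libraries, 1 library each; lines are exact Poisson 95% intervals. Marco stood at 31.6 and 295 CPM, and Lyz2 at 807 and 91.4 CPM.

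In endothelial-like nuclei (clusters 5 and 11; 183 in Aza-TdC, 180 in MASLD) the sinusoidal identity list had a median of 0.020 (-0.88 to 0.16) and the capillarization and activation list 0.46 (-1.16 to 1.59). The sinusoidal median was 0.48 with at most 1% mitochondrial UMIs. The sinusoidal list went both ways, with 2 of 19 measured members at 1 or more and 4 at -1 or less. Of its members, Fcgr2b had -1.56 (-1.88 to -1.24) and Lyve1 -2.23 (-2.98 to -1.55). Rspo3 and Wnt9b of the same list had 2.07 (1.65 to 2.503) and 2.58 (1.40 to 3.99). The capillarization list had 4 of 14 measured members at 1 or more and 3 at -1 or less. Its members Vwf, Edn1 and Icam1 had 2.21 (1.75 to 2.69), 2.82 (1.85 to 3.95) and 1.59 (0.71 to 2.55). Among the 5 highest were Sntg1 at 5.79 (4.41 to 7.68), Adamtsl1 at 4.26 (3.42 to 5.23), Nuak1 at 3.92 (2.48 to 5.85) and Myrip at 4.05 (2.41 to 6.38). Cluster 11, which holds Vwf and Rspo3 among its leading genes, had 5 MASLD and 38 Aza-TdC nuclei. With it left out of the class, Rspo3 had -0.90 over 10 UMIs in Aza-TdC and 26 in MASLD. Icam1 had 1.07 over 18 UMIs in Aza-TdC and 12 in MASLD, with an interval including 0. Vwf, Wnt9b, Edn1, Sntg1, Adamtsl1, Nuak1 and Myrip then had at most 5 UMIs in each library, and the list medians were -0.24 and -0.87. The 5 lowest were Lyve1 with Mup11, Mup17, Hbb-bs and Hbb-bt, the last 4 best known from hepatocytes or red blood cells. In stellate-like nuclei (83 in Aza-TdC, 106 in MASLD; under 100 in 1 library, so no single genes are named) the fibrosis list had -0.30 (-0.79 to 0.43) with percentile 0.5, and the quiescence list 0.15 (0.071 to 0.35), which changed sign under 4 alternatives. With at most 1% mitochondrial UMIs the fibrosis median turned to 0.27, inside its main interval over members. In T and NK-like nuclei (41 in each) the T cell list had 0.94 (-0.43 to 1.64) over 5 members. It was 0.59 in the nuclei that stayed T and NK-like at Leiden resolution 2, and -0.21 with 0.5 added UMIs and no minimum count beyond 1 UMI.

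The last comparison asked whether Aza-TdC ratios ran opposite to diet ratios. A tally chosen after seeing the data covered the 24 genes named by size for MASLD against SD. Their Aza-TdC to MASLD ratio ran opposite to the diet ratio in 12 and in the same direction in 5 (intervals excluding 0), and had an interval including 0 in 7. All 24 lay on the same side of SD in Aza-TdC as in MASLD. These genes were picked by their MASLD to SD ratio, and the ratios share the MASLD or the SD library, which favours both outcomes. No value under no change was simulated for this tally. With clusters 13 and 14 left out, the Aza-TdC to MASLD ratio of Fut2, Ephb2, Hsd3b5, Serpina1e and Pdgfrl changed sign. Its interval then included 0 for Ephb2, Hsd3b5 and Serpina1e. Ly6d had 0 UMIs in SD, so its log2 ratios to SD are bounds. Set over the diet log2 ratio, the log2 ratio of Aza-TdC to SD was 0.069 for Cidea (0.45 to SD) and from 0.564 to 1.157 for the others, such as Fut2 (8.05), Plscr4 (4.38), Cd36 (4.53), Rbfox1 (7.04), Avil (-2.91) and Pdgfrl (-4.08). Across 13548 genes in hepatocyte-like nuclei, genes being no independent replicates, the 2 log2 ratios had a correlation of -0.443 and a covariance of -0.196. Both comparisons share the MASLD library, and simulated exchangeable libraries gave -0.502 and -0.295. Exchangeable libraries give about that correlation by construction. The log2 ratios had unequal standard deviations, 0.86 for MASLD to SD, 0.514 for Aza-TdC to MASLD and 0.782 for Aza-TdC to SD. The libraries thus did not behave as exchangeable, and the simulation cannot decide whether the opposite direction exceeds what a shared library gives. With the MASLD nuclei split at random between the comparisons the correlation was -0.414, so counting error of shared nuclei accounts for little of it. Both parts still come from 1 library.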

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

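No test was run on the results in this part. A signal in nuclei outside the comparisons drew attention to a shallow cluster without a name (cluster 16), which held 74 nuclei in MASLD, 77 in Aza-TdC and 0 in SD, with a median of 882.0 UMIs per nucleus. The smallest SD barcode held 1546 UMIs, and no nuclei of any type lay under that depth in SD, which largely fixes its 0. The barcodes left out by the filter also held a signal absent from SD, with 202 barcodes in MASLD and 7 in Aza-TdC over the limit of 5% mitochondrial UMIs and 0 in SD.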

How the results depend on the processing

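No paired analysis was possible because each group has 1 library. Choices made before the data were examined covered the filters, doublets, resolution, scaling and minimum counts. The common floor, the top 6% of doublet scores, the strict naming of clusters, the matched mitochondrial share, the subtraction of hepatocyte RNA, the removal of dendritic nuclei or of cluster 11, and clusters made without the macrophage lists were chosen after seeing the data. Values below are class shares that moved beyond counting error, list medians of both main comparisons that moved outside their main interval over members, and sign changes of values whose main interval excluded 0. List medians whose main interval included 0 changed sign in 61 further cases, 54 of them inside that interval. For Aza-TdC against MASLD these include the endothelial-like sinusoidal (0.020 to -0.24) and capillarization medians (0.46 to -0.87) without cluster 11 and the T cell median (0.94 to -0.21) with 0.5 added UMIs. The cause was not tested for any of them. Named genes that moved without changing sign, most under strict naming (187), matched mitochondrial share (175) and median-ratio scaling (87), are not listed. For 35 combinations of gene and alternative, over 19 genes, too few UMIs were left for a value. Above the common floor, cluster 11 (13 SD, 4 MASLD and 29 Aza-TdC nuclei there) joined the stellate-like class. Low numbers of nuclei limit the small classes, since SD held 31 macrophage-like and 77 stellate-like nuclei. Median-ratio scaling moved the median gene by -0.13 and 0.096 in hepatocyte-like, 0.20 and -0.087 in endothelial-like, 0.32 and 0.059 in macrophage-like and 0.18 and -0.19 in stellate-like nuclei (MASLD against SD, then Aza-TdC against MASLD). A minimum of 100 UMIs, 0.5 added UMIs and a total without the 20 most abundant genes moved no list median outside its interval over members; that of the T cell list spans 5 members.

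With classes by each nucleus's own markers, shares were 97.6% in SD, 93% in MASLD and 93.2% in Aza-TdC for hepatocyte-like nuclei, 1.09% in SD, 2.22% in MASLD and 1.71% in Aza-TdC for endothelial-like nuclei, 0.14% in SD, 2.01% in MASLD and 3.31% in Aza-TdC for macrophage-like nuclei, 0.77% in SD and 1.28% in MASLD for stellate-like nuclei, 0.112% in SD, 0.193% in MASLD and 0.211% in Aza-TdC for T and NK-like nuclei and 0.21% in SD, 0.535% in MASLD and 0.514% in Aza-TdC for mesothelial-like nuclei. List medians were 0.044 for stellate quiescence (Aza-TdC against MASLD, stellate-like nuclei) and 0.63 for Kupffer identity (Aza-TdC against MASLD, macrophage-like nuclei). With Leiden resolution 2, shares were 88.9% in MASLD and 89.2% in Aza-TdC for hepatocyte-like nuclei, 0.252% in SD and 1.58% in MASLD for macrophage-like nuclei and 0.387% in MASLD and 0.382% in Aza-TdC for T and NK-like nuclei. List medians were 0.38 for Kupffer identity and -0.91 for lipid-associated and recruited macrophage (Aza-TdC against MASLD, macrophage-like nuclei). With a minimum of 1000 UMIs, shares were 91.5% in MASLD and 91.6% in Aza-TdC for hepatocyte-like nuclei and 0.287% in MASLD and 0.296% in Aza-TdC for T and NK-like nuclei. With no filter on nuclei, shares were 86.5% in MASLD for hepatocyte-like nuclei, 3.61% in MASLD for endothelial-like nuclei, 6.28% in MASLD and 5.5% in Aza-TdC for macrophage-like nuclei and 1.14% in MASLD for mesothelial-like nuclei. With at most 1% mitochondrial UMIs, shares were 94% in MASLD and 90.6% in Aza-TdC for hepatocyte-like nuclei, 0.727% in MASLD and 1.79% in Aza-TdC for endothelial-like nuclei, 1.91% in MASLD for macrophage-like nuclei, 0.776% in MASLD for stellate-like nuclei, 0.113% in MASLD and 0.308% in Aza-TdC for T and NK-like nuclei and 0.162% in MASLD and 0.589% in Aza-TdC for mesothelial-like nuclei. List medians were 0.13 for fibrosis and extracellular matrix and -0.078 for stellate quiescence (MASLD against SD, stellate-like nuclei), -0.43 for sinusoidal endothelial identity (MASLD against SD, endothelial-like nuclei), 0.56 for Kupffer identity (Aza-TdC against MASLD, macrophage-like nuclei) and 0.48 for sinusoidal endothelial identity (Aza-TdC against MASLD, endothelial-like nuclei). Dnase1l3 at -0.032 (MASLD against SD, endothelial-like nuclei) changed sign. The interval of Dnase1l3 there includes 0. With no doublets left out, shares were 87.9% in MASLD and 88.7% in Aza-TdC for hepatocyte-like nuclei, 0.252% in SD and 2.53% in MASLD for macrophage-like nuclei and 0.588% in SD, 1.65% in MASLD and 0.83% in Aza-TdC for T and NK-like nuclei. List medians were 0.57 for Kupffer identity (Aza-TdC against MASLD, macrophage-like nuclei) and -0.026 for Kupffer identity with a changed sign (Aza-TdC against SD, macrophage-like nuclei). With a common floor of 1546 UMIs, shares were 93.6% in MASLD and 93.4% in Aza-TdC for hepatocyte-like nuclei, 1.63% in MASLD and 1.04% in Aza-TdC for endothelial-like nuclei, 2.8% in MASLD and 3.56% in Aza-TdC for macrophage-like nuclei, 1.19% in MASLD for stellate-like nuclei and 0.203% in MASLD and 0.193% in Aza-TdC for T and NK-like nuclei. List medians were -0.076 for stellate quiescence with a changed sign (Aza-TdC against MASLD, stellate-like nuclei). Nrg1 at 2.87 and Rspo3 at 3.002 (MASLD against SD, endothelial-like nuclei) and Sntg1 at -0.78 and Rspo3 at -1.59 (Aza-TdC against MASLD, endothelial-like nuclei) changed sign. The interval of Sntg1 there includes 0. UMIs were Nrg1 10 against 1, Rspo3 22 against 2 and Sntg1 2 against 5. With clusters 13 and 14 unnamed (every foreign leading marker counted), shares were 6.39% in MASLD and 88.8% in Aza-TdC for hepatocyte-like nuclei. List medians were 1.18 for cell cycle, -1.68 for periportal zone, 1.79 for pericentral zone and -0.041 for sinusoidal endothelial identity (MASLD against SD, hepatocyte-like nuclei) and -0.65 for cell cycle, 0.37 for interferon response, -0.78 for unfolded protein and integrated stress response, -0.073 for CAR, PXR and AHR cytochromes, -0.98 for male-biased liver genes, 1.64 for periportal zone, -2.35 for pericentral zone and -0.81 for hepatocyte dedifferentiation and ductular (Aza-TdC against MASLD, hepatocyte-like nuclei). Lhpp at 1.01 (MASLD against SD, hepatocyte-like nuclei) and Abcc4 at -0.68, Brdt at -0.40, Cyp2c29 at -0.78, Cyp2c40 at -0.56, Cyp2c54 at -0.38, Fcgr2b at 1.40, Fut2 at 0.92, Ephb2 at 0.10, Hsd3b5 at -0.33, Serpina1e at 0.33 and Pdgfrl at 1.16 (Aza-TdC against MASLD, hepatocyte-like nuclei) changed sign. The intervals of Brdt, Cyp2c40, Fcgr2b, Ephb2, Hsd3b5 and Serpina1e there include 0. UMIs were Fcgr2b 40 against 1. With shares taken over nuclei that are not hepatocyte-like, shares were 41.1% in SD, 26% in MASLD and 24% in Aza-TdC for endothelial-like nuclei, 11.1% in SD, 34.9% in MASLD and 41.9% in Aza-TdC for macrophage-like nuclei, 27.5% in SD, 15.3% in MASLD and 10.9% in Aza-TdC for stellate-like nuclei, 10.0% in SD, 5.92% in MASLD and 5.37% in Aza-TdC for T and NK-like nuclei and 10.4% in SD, 7.21% in MASLD and 7.73% in Aza-TdC for mesothelial-like nuclei. With the top 6% of doublet scores left out, shares were 3.06% in MASLD for macrophage-like nuclei and 0.378% in MASLD for T and NK-like nuclei. List medians were -0.029 for stellate quiescence with a changed sign (Aza-TdC against MASLD, stellate-like nuclei). With nuclei matched for mitochondrial share, list medians were -0.10 for sinusoidal endothelial identity and 0.34 for nuclear and RNA quality signs (MASLD against SD, hepatocyte-like nuclei) and 0.098 for sinusoidal endothelial identity and -0.38 for nuclear and RNA quality signs (Aza-TdC against MASLD, hepatocyte-like nuclei). Cyp1a1 at 0.32, Fos at 0.51 and Serpina1e at 0.60 (Aza-TdC against MASLD, hepatocyte-like nuclei) changed sign. The intervals of Cyp1a1 and Fos there include 0. UMIs were Cyp1a1 7 against 1 and Fos 8 against 1. With hepatocyte RNA subtracted, list medians were -0.090 for stellate quiescence (MASLD against SD, stellate-like nuclei), 0.003 for stellate quiescence (Aza-TdC against MASLD, stellate-like nuclei) and -0.003 for fibrosis and extracellular matrix with a changed sign and -0.049 for stellate quiescence with a changed sign (Aza-TdC against SD, stellate-like nuclei). With median-ratio scaling, list medians were -0.17 for PPARA targets and fatty acid oxidation and -0.051 for glucose metabolism and insulin signalling (Aza-TdC against MASLD, hepatocyte-like nuclei) and -0.031 for stellate quiescence with a changed sign (Aza-TdC against MASLD, stellate-like nuclei). With mean over nuclei of each nucleus's CPM, list medians were -0.053 for stellate quiescence with a changed sign (Aza-TdC against MASLD, stellate-like nuclei). With cluster 11 left out of the endothelial-like class, Nrg1 at 2.60 and Rspo3 at 2.98 (MASLD against SD, endothelial-like nuclei) and Sntg1 at -1.52 and Rspo3 at -0.90 (Aza-TdC against MASLD, endothelial-like nuclei) changed sign. The intervals of Nrg1, Sntg1 and Rspo3 (Aza-TdC against MASLD) there include 0. UMIs were Nrg1 10 against 1, Rspo3 26 against 2 and Sntg1 1 against 4. With at least 500 UMIs, the correlation of both sets of ratios was -0.425. With MASLD nuclei split in 2, the correlation of both sets of ratios was -0.414.

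Of 2424 counts of list members past a log2 ratio of 1 under the alternatives, 269 differed from the main count by more than 1.5 times, spread over 81 combinations of list, class and comparison. The counts the report leads with, where at least 5 members were counted, changed as follows. The 9 higher members of the interferon response list for MASLD against SD in hepatocyte-like nuclei became 5 with median-ratio scaling. The 11 higher members of the interferon response list for Aza-TdC against MASLD in hepatocyte-like nuclei became 5 with clusters 13 and 14 unnamed (every foreign leading marker counted) and 6 with nuclei matched for mitochondrial share. The 5 higher members of the female-biased liver genes list for Aza-TdC against MASLD in hepatocyte-like nuclei became 1 with clusters 13 and 14 unnamed (every foreign leading marker counted) and 8 with median-ratio scaling. The 5 lower members of the male-biased liver genes list for Aza-TdC against MASLD in hepatocyte-like nuclei became 11 with clusters 13 and 14 unnamed (every foreign leading marker counted). The 11 higher members of the fibrosis and extracellular matrix list for MASLD against SD in stellate-like nuclei became 7 with classes by each nucleus's own markers, 2 with at most 1% mitochondrial UMIs, 3 with at least 100 UMIs and 5 with hepatocyte RNA subtracted. The 8 higher members of the Kupffer identity list for Aza-TdC against MASLD in macrophage-like nuclei became 1 with Leiden resolution 2, 5 with classes by each nucleus's own markers, 13 with no filter on nuclei, 2 with at most 1% mitochondrial UMIs and 3 with no doublets left out. The 14 higher members of the lipid-associated and recruited macrophage list for MASLD against SD in macrophage-like nuclei became 6 with Leiden resolution 2. The 14 lower members of the lipid-associated and recruited macrophage list for Aza-TdC against MASLD in macrophage-like nuclei became 7 with Leiden resolution 2 and at least 100 UMIs.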

Other observations

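The macrophage share tests, the free RNA test, the tests of macrophage states, the tests of dendritic nuclei at Leiden resolution 2 and by their own markers alone, the parts of the cytoplasmic RNA test by comparison and by list, and the spreads set beside each ratio of medians were chosen after the result was seen. The interferon list was also read in other classes, a choice made after its hepatocyte value was seen. For Aza-TdC against MASLD its median log2 ratio was 0.97 (0.53 to 1.64) with 13 of 14 measured members above 0 in endothelial-like nuclei, 0.60 (0.18 to 1.12) with 24 of 29 measured members above 0 in macrophage-like nuclei and 0.59 (-0.15 to 1.03) with 8 of 11 measured members above 0 in stellate-like nuclei. For MASLD against SD the medians were -0.15, -0.13 and 0.30 in the same order. Hepatocyte RNA was not subtracted from these values. In MASLD and Aza-TdC, hepatocyte markers stood at 0.818 and 0.572 times their hepatocyte level in endothelial-like nuclei. The values were 0.477 and 0.412 in macrophage-like and 0.466 and 0.424 in stellate-like nuclei. Free hepatocyte RNA, where the list median was 0.68 for Aza-TdC against MASLD, can thus contribute. The pancreatic enzyme genes Cpb1, Ctrb1 and Prss2 had 75, 55 and 37 UMIs in hepatocyte-like nuclei of MASLD, or 1.81, 1.33 and 0.894 CPM. They had 0 UMIs in its endothelial-, macrophage- and stellate-like nuclei, where 3 counts correspond to 6.47, 4.13 and 9.75 CPM, so a difference between these classes was not detectable.

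The share of macrophage-like nuclei was 8.29 times as high in MASLD as in SD. A lower smallest UMI total in MASLD would bring the ratio to 1 under a common floor, but its lower bound there was 3.95, and nuclei rich in mitochondrial RNA would do so under a limit of 1%, where its lower bound was 2.71. Both argue against these as the whole cause, although the ratio itself was smaller, at 5.71 and 4.00, and over nuclei that are not hepatocyte-like the shares were 34.9% in MASLD and 11.1% in SD. With 1 library per group, diet cannot be told apart from the animals or the tissue behind each library, because no spread between animals was measured.

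The lipid droplet list and the list of fatty acid uptake and PPARG targets were higher in MASLD and lower with Aza-TdC in hepatocyte-like nuclei. Cytoplasmic RNA left with the MASLD nuclei was tested in nuclei matched for mitochondrial share, where the smallest of the 4 ratios of a list median to its main size was 0.883. The RNA quality list kept 0.376 and 0.28, but it holds mitochondrial genes, which this matching by itself evens out. Its fall therefore does not show that other cytoplasmic RNA was removed. For MASLD against SD the smaller ratio, that of the uptake list, was 0.883 with lower bounds above 0.5. For Aza-TdC against MASLD the lipid droplet list kept 1.062 with lower bounds of 0.958 and 0.87. Both argue only against cytoplasmic RNA that follows the mitochondrial share. In the latter comparison the uptake list kept 0.918 with a resampled lower bound of 0.29, so cytoplasmic RNA cannot be told apart for it. Scaling moved the median gene of hepatocyte-like nuclei by at most 0.128, less than the smallest list median. An effect of the diet on lipid storage genes stays a hypothesis that may hold, untested with 1 library per group.

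In macrophage-like nuclei the Kupffer identity list was higher and the recruited list lower with Aza-TdC; hemoglobin transcripts were lower as well, and carry-over of blood was not tested. Subtracting hepatocyte RNA left 0.87 of the Kupffer identity median, after a first version with the total kept had left 1.001, and leaving out the 5 SD and 22 MASLD nuclei whose own markers were highest for dendritic cells left 0.886, which argues against hepatocyte RNA and against those nuclei as the whole cause. Dendritic nuclei in general cannot be told apart, since that removal was too narrow. A cluster at Leiden resolution 2 scored higher for dendritic than Kupffer markers (4.95 against 4.60), though its leading genes Lyz2 and Gpnmb are macrophage markers. This cluster held 136 of the MASLD and 30 of the Aza-TdC macrophage-like nuclei, and without it 0.379 of the Kupffer identity median remained. With at most 1% mitochondrial UMIs 0.554 remained. Its lower bound of 0.512, read alone, would have argued against nuclei rich in mitochondrial RNA. A resampled bound of 0.42, added after the first had been seen, leaves them open. Nuclei were also clustered and named again under that limit. Macrophage-like MASLD nuclei went from 242 to 118 and MASLD nuclei without a name from 74 to 142. The 0.554 can thus reflect a changed class as well and decides nothing on nuclei rich in mitochondrial RNA. A different mix of macrophage states may also hold and cannot be told apart as a cause. The 0.379 comes from a cluster made partly from the listed genes. In the largest cluster made without them, 1.601 of the Kupffer identity and 1.122 of the recruited median remained. That cluster held 190 MASLD and 315 Aza-TdC nuclei and so most of the class. Another cluster, whose leading genes hold Diaph3 and Ect2 of the cell cycle list, held 51 MASLD and 4 Aza-TdC macrophage-like nuclei. The mix thus differed between these libraries, but both medians remained without those nuclei.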
